A study of Mus musculus with 7 samples.

How the data were processed

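RNA from cultured mouse prostate cancer cells was hybridised to 7 one-colour oligonucleotide arrays, 3 for PKO cells and 4 for Myc-Cap cells. The series' value table gave 1 value for each of 45101 probe sets on each array; scanner files were not used here. The deposited values were on a log2 scale: they ran from 2.60 to 14.8, none was below 0, and 2 raised to them gave the range of scanner intensities. MAS5 was named, without a version, per the submitters' processing notes. The normalization stayed unsettled, because the deposited log2 values had nearly equal distributions. Values of equal rank lay within 0.133 of each other over the 7 arrays. The 2% trimmed means of the linear values, by contrast, ran from 739 to 762. The median SD between Myc-Cap arrays was 0.105 for probe sets with a mean below 5. Differences between the lines were therefore taken on a scale already made common to the arrays by the authors, by a step that is not given in the sources used here.

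Deposited values were taken to the linear scale, an offset of 30 (the 25th percentile of all values) was added, and log2 was taken. No further normalization was applied. A fold is on this offset scale, which for a given probe set understates the ratio of its signals when it is low in either line. The size and order of the largest differences depend on the offset, the probe set chosen and background, since these genes are low in one line. Probe sets were named with the platform's annotation table, in which 34958 had 1 gene symbol, 932 had several and 9211 were not listed. Probe sets with several symbols or none were not used for genes, and control probe sets were left out. Symbols were compared with the names of the GRCm38.p6 annotation by gene identifier; 34741 of 34945 probe sets matched, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over all 7 arrays. A gene was tested if that mean lay above the 40th percentile of the means of all probe sets, 6.52, which left 12356 genes. No probe set was named Pten or Ar in the annotation table, so these 2 genes were not analysed here, and the Pten deficiency in the label of PKO cells was not checked.

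The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the mean), two-sided, with Benjamini-Hochberg adjustment over the genes tested. Differences are PKO minus Myc-Cap throughout. A gene was called when its adjusted p was under 0.05 and its absolute log2 difference was at least 1. Levels are given as mean ± SD over the arrays of a line on the log2(value + 30) scale. On simulated data for the 12356 genes, with 200 genes changed, the procedure gave an adjusted p under 0.05 to 78% of genes changed by 0.25 and to 100% of those changed by 0.5. It called 100% of those changed by 1.5 or by 3. Of the unchanged genes, 14 had an adjusted p under 0.05 and 0 were called. The simulated noise was independent between genes and held no shift shared by the arrays of a line. Changes between 0.5 and 1.5 were not tried. These rates therefore need not hold for the real arrays, where far more genes differed.

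The design, the tests, 23 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 22 lists, and again with an estimated correlation. The estimate was 0.126 for ribosome biogenesis genes and 0.137 for cell cycle genes. It was -0.00076 for interferon-stimulated genes, whose adjusted p in camera also rose, from 3.70e-16 to 0.00380. A larger p with this setting is therefore not by itself a sign that the members of a list move together. The camera test compares the members of a list with all other genes, so a list can be placed above the rest of the genes while its own mean is near 0. The rule named Pten, Ar and Myc, the 12 called genes with the largest rise and the 12 with the largest fall whose arrays did not overlap between the lines (predicted and unnamed genes left out), and up to 4 called members of each list with the largest absolute difference. Further genes, such as the exceptions of a list, were named after their values were seen. Array quality was compared with an exact permutation test over all 35 splits of the arrays into 3 and 4, two-sided.

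The labels call the arrays of a line biological replicates and do not say whether they came from separate cultures. If they did not, the p-values measure only the spread between these arrays, which may be technical. Each group is a single cell line. Even with separate cultures the p-values would not measure the spread between different Pten-deficient or different MYC-driven lines. The number of arrays limits the precision of every difference. No array dates were used here, so the fit has no term for processing batch. Alternatives covered quantile normalization, scaling to a common median, no offset or 4 times the offset, no filter or a 70th percentile filter, the mean of a gene's probe sets, probe sets tested one by one, limma's treat, eBayes without trend, array weights, the replicate number as a block, no size threshold, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.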

Results

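Gene expression was profiled in cell lines of mouse prostate cancer, on 3 arrays of PKO cells and 4 arrays of Myc-Cap cells. PKO cells are a Pten-deficient line described as androgen-independent. Myc-Cap cells are an androgen-dependent line from a prostate tumour of a mouse with a human MYC transgene. Both lines were grown in the same serum-containing medium and were untreated. Array medians ran from 6.53 to 6.60 on the deposited log2 scale. Across the 12356 genes tested, which are not independent replicates, arrays of the same line correlated at 0.998 to 0.999 and arrays of different lines at 0.759 to 0.763. The comparison asked how the expression profile of PKO cells differs from that of Myc-Cap cells.

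The 12 genes with the largest rises in PKO cells lay between 5.35 and 6.09 in Myc-Cap cells and between 12.76 and 13.70 in PKO cells. Lists of interferon-stimulated genes and mesenchymal transition genes were higher in PKO cells, also with an estimated correlation (adjusted p = 0.00380 and 0.0145). Lists of ribosome biogenesis and cell cycle genes were lower in PKO cells at camera's preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.0814 for each). Dpysl3, a cytoskeletal regulator of neurite outgrowth, was 327-fold higher in PKO cells, at 13.70 ± 0.016 (SD, n = 3) against 5.35 ± 0.014 (SD, n = 4). Its other probe sets were higher by less, with log2 differences of 4.90 and 3.87. Aldh1a1, an enzyme of retinoic acid synthesis, was 426-fold lower, at 5.39 ± 0.0077 (SD, n = 3) against 14.13 ± 0.033 (SD, n = 4). In the limma fit 3294 genes were called (26.7% of those tested), 1655 higher and 1639 lower in PKO cells, so that 50.2% were higher. The median difference of all genes tested was -0.11. Differences of at least 16-fold were more often rises than falls, with 344 called genes higher and 103 lower. The arrays of the lines did not overlap for any of the 3294 called genes, and for 85.1% of the genes tested, where chance gives 5.71%. With a filter at the 70th percentile 7833 genes were tested and 1742 called, 36.7% of them higher in PKO cells. That filter, on a mean over 4 Myc-Cap and 3 PKO arrays, removes genes low only in Myc-Cap cells more readily than the reverse. Without the size threshold 10612 genes were called, 42.3% of them higher.

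The 12 largest rises ran from 7.34 to 8.35 on the log2 scale. Beside Dpysl3 they included Gfra2, a co-receptor for neurturin (8.04, SE 0.052, adjusted p = 7.63e-19), and Dpysl2 (7.74, SE 0.094), a relative of Dpysl3. Trim30a, an interferon-inducible gene, was higher by 7.71. The others were the collagen genes Col6a1 (7.58) and Col3a1 (7.54), the guidance cue Sema3a (7.55), the kinase Dclk1 (7.55), the adhesion receptor Vcam1 (7.34), the repressor of epithelial genes Zeb1 (7.34), the tetraspanin Cd81 (7.34) and the glutathione transferase Mgst1 (7.34). The gene value of Gfra2 rests on a probe set type that can detect related transcripts, and its 4 other probe sets were higher by 2.62 to 5.28. A second probe set of Dpysl2 did not move with the first (-0.16), nor did one of Mgst1 near background (0.092).

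The 12 largest falls ran from -6.70 to -8.74. Aldh1a7 (-7.94) is a close paralog of Aldh1a1, so signal from shared sequence makes its value uncertain. The potassium channel Kcnk1 was lower (-7.87, at 5.49 ± 0.029, SD, n = 3, against 13.35 ± 0.051, SD, n = 4; adjusted p = 3.49e-19). The others were the matrix protein gene Efemp1 (-7.21), the protease inhibitor genes Wfdc12 (-7.16) and Wfdc6a (-6.70), the mitochondrial outer membrane gene Fundc2 (-7.00), the claudin Cldn10 (-6.93), Kank4 (-6.83), the cysteine dioxygenase Cdo1 (-6.81), Zbtb8b (-6.72) and the adhesion gene Mpzl2 (-6.70). Both further probe sets of Fundc2 were also lower (-2.55 and -4.20).

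**Figure D1:**
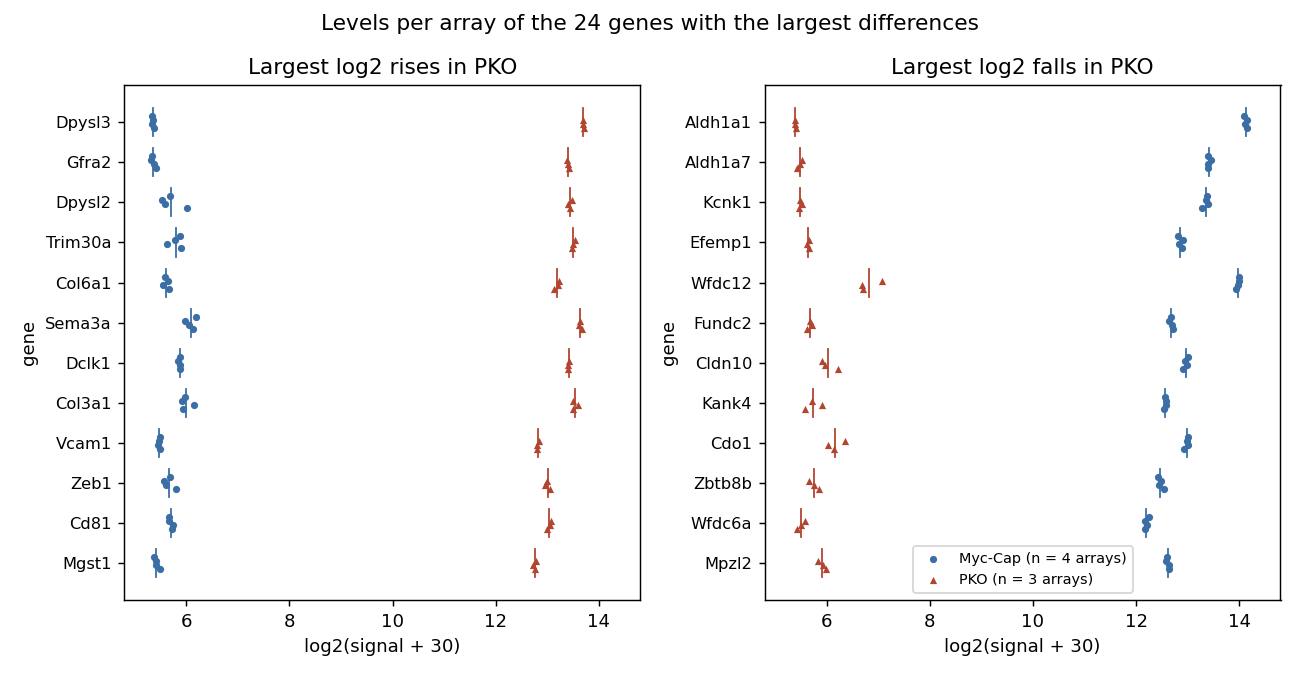
Levels of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) in PKO cells, on the x axis as log2(signal + 30); circles are the 4 Myc-Cap arrays, triangles the 3 PKO arrays and vertical lines their means. No gene has overlapping arrays, and the means lie between 6.70 and 8.74 log2 units apart.

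Of Pten, Ar and Myc, Myc was the gene with a named probe set. Mouse Myc was at 9.92 ± 0.051 (SD, n = 3) in PKO cells and 9.003 ± 0.20 (SD, n = 4) in Myc-Cap cells. It was 1.88-fold higher in PKO cells (0.91, SE 0.088, adjusted p = 2.88e-07), under the size threshold for a call. The PKO arrays read 9.95, 9.86 and 9.94, and the Myc-Cap arrays 8.71, 9.08, 9.12 and 9.10. Whether this probe set also detects the human transgene was not examined.

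Control and quality values of the arrays differed between the lines, with 0 of 6 measures at an adjusted p under 0.05, and stand beside every group of genes described here. Hybridization controls, bacterial and phage transcripts added before hybridization, averaged 12.73 ± 0.031 (SD, n = 3) on PKO arrays and 12.48 ± 0.012 (SD, n = 4) on Myc-Cap arrays (exact permutation p = 0.0286, the smallest that 35 splits allow, adjusted p = 0.0572 over 6 measures). Poly-A controls, added to the RNA, were lower on PKO arrays (difference -0.41, exact permutation p = 0.0286, adjusted p = 0.0572). Array medians were higher by 0.052 (exact permutation p = 0.0286, adjusted p = 0.0572) and the interquartile range was lower, at 4.53 against 4.66 (exact permutation p = 0.0571, adjusted p = 0.0856). The 3-prime to 5-prime log2 ratio, a sign of RNA integrity, differed by -0.047 for Gapdh and 0.048 for beta-actin (exact permutation p = 0.0857 and 0.114, adjusted p = 0.103 and 0.114).

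Interferon-stimulated genes, the antiviral genes that interferon signalling switches on, were higher in PKO cells almost without exception. Of 38 tested members 37 were called higher and 0 lower, with a median difference of 3.77 (camera adjusted p = 3.70e-16, and 0.00380 with an estimated correlation). Parp12 was 79.4-fold higher, and Usp18, which removes ISG15 from proteins and dampens interferon receptor signalling, was 76.3-fold higher (12.20 ± 0.029, SD, n = 3, against 5.95 ± 0.090, SD, n = 4). Rtp4 was higher by 6.07 and Oasl2 by 5.69. Ifit2, the member that was not called, was at 10.9 in both lines (difference 0.021). Of 7 tested immune cell markers 1 was called higher, the MHC class II invariant chain gene Cd74 (2.37), and 0 were called lower. The mean of the immune list was 0.11, its median -0.14, and camera placed it lower than other genes (adjusted p = 0.919, and 0.921 with an estimated correlation). With any of the 4 Myc-Cap arrays left out, 7 or 8 immune markers were tested and 2 were called higher.

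Genes of MHC class I antigen presentation were higher in PKO cells, with 10 of 18 tested members called higher and 0 lower (median 1.23, camera adjusted p = 2.81e-07). The call was lost with an estimated correlation (adjusted p = 0.0544). Nlrc5, the transactivator of MHC class I genes, was 34.6-fold higher, and the immunoproteasome subunits Psmb9 and Psmb8 were higher by 4.81 and 4.67. The peptide transporter gene Tap1 was higher by 3.98, while another probe set of it above the filter differed by 0.35. The list of chemokines, cytokines and NF-kappaB targets had 23 of 34 tested members called higher and 2 lower (median 1.83, camera adjusted p = 1.11e-06, and 0.0145 with an estimated correlation). Vcam1, the matrix metalloprotease gene Mmp9 (7.31), the chemokine gene Cxcl12 (6.17) and Tnfaip2 (5.97) had its largest differences. The members called lower were Lcn2 (-2.66) and Saa3 (-1.03), named after their values were seen. Without Myc-Cap replicate 2, or without PKO replicate 2, 1 member was called lower.

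Mesenchymal transition genes were higher in PKO cells: 18 of 29 tested members were called higher and 1 lower (median 3.14, camera adjusted p = 4.68e-09, and 0.0145 with an estimated correlation). Beside Zeb1, the collagen cross-linking enzyme Lox was 137-fold higher (12.83 ± 0.033, SD, n = 3, against 5.73 ± 0.046, SD, n = 4), and the matrix genes Tgfbi and Thbs1 were higher by 6.80 and 6.69. The member called lower was the integrin Itgb3 (-3.48), named after its value was seen. Vim was high in both lines, at 14.45 in PKO and 13.86 in Myc-Cap cells, and its difference of 0.59 was under the size threshold. Fibroblast markers moved with them, with 12 of 15 tested members called higher and 1, Fbln1 (-1.95), lower (median 4.17, camera adjusted p = 8.35e-06, lost with an estimated correlation at adjusted p = 0.0544). Col6a1, Col3a1, the proteoglycan gene Dcn (7.31) and Col6a2 (7.14) led this list. Col1a1 was higher by 6.69. Col1a2 differed by 0.32, under the size threshold for a call, with its 3 probe sets near background in both lines. Col1a2 was at 6.88 ± 0.19 (SD, n = 3) in PKO cells. Endothelial markers had 4 tested members and were not tested as a list; Flt1 (4.91) and Plvap (3.11) were called higher.

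Epithelial junction and identity genes split, with 6 of 29 tested members called higher and 10 lower in PKO cells. The median was -0.57 and camera placed the list lower (adjusted p = 0.247, and 0.281 with an estimated correlation). Grhl2, a transcription factor of epithelial identity, was 74.3-fold lower (5.81 ± 0.047, SD, n = 3, against 12.02 ± 0.043, SD, n = 4), and Lsr, of tricellular junctions, was also lower (-4.46). The desmosomal cadherin genes Dsc2 and Dsg2 were higher by 5.07 and 4.08. Cdh1 was also higher, by 2.45 (8.14 in PKO cells against 5.69, near background, in Myc-Cap cells). The other probe sets of Grhl2, at low signal, differed by -1.29, -0.70 and -0.33. Without PKO replicate 3, 26 members were tested, 3 called higher and 11 lower. The list then had a mean of -0.74 and passed camera (adjusted p = 0.0478). With a 70th percentile filter it also passed, at a mean of -2.08 (camera adjusted p = 0.0395). That filter acts on the mean over 4 Myc-Cap and 3 PKO arrays. It therefore removes genes that are high only in PKO cells more readily than genes that are high only in Myc-Cap cells. This pass does not show that the list as a whole was lower. Without PKO replicate 1 or PKO replicate 2, 27 members were tested and 4 called higher. The filter uses the mean over the arrays kept, so leaving out a PKO array can remove genes that are high in PKO cells.

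Prostate luminal markers had 4 of 11 tested members called higher and 3 lower (camera adjusted p = 0.662, median 0.12, and 0.768 with an estimated correlation). The luminal keratin genes Krt18 and Krt8 were 97.9-fold and 13.8-fold higher in PKO cells, while Psca was 52.9-fold lower and the receptor gene Fgfr2 was also lower (-4.22). Prostate basal markers had 6 of 17 tested members called higher and 3 lower (median 0.38, camera adjusted p = 0.117, and 0.215 with an estimated correlation). Trp63, the transcription factor of basal cells, was 49.4-fold higher (12.58 ± 0.053, SD, n = 3, against 6.96 ± 0.090, SD, n = 4) and the growth factor gene Nrg1 was higher by 5.48. Krt6a (-3.19) and the laminin chain gene Lama3 (-2.90) were lower. Without a filter on low values the basal list passed (adjusted p = 0.0403).

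MYC targets of ribosome biogenesis were lower in PKO cells: 31 of 47 tested members were called lower and 0 higher (median -1.20, camera adjusted p = 4.21e-11). The call was lost with an estimated correlation (adjusted p = 0.0814). Cad, which starts pyrimidine synthesis, was 6.33-fold lower and the spermidine synthase gene Srm 4.78-fold lower. Polr1b, which encodes a subunit of RNA polymerase I (-2.20), and Rrp9, of ribosomal RNA processing (-1.88), were also lower. Cell cycle genes were lower too, with 28 of 43 tested members called lower and 0 higher (median -1.24, camera adjusted p = 7.14e-11, lost with an estimated correlation at adjusted p = 0.0814). Mybl2, a transcription factor of the cell cycle, was 11.2-fold lower (6.49 ± 0.090, SD, n = 3, against 9.98 ± 0.10, SD, n = 4). The replication licensing gene Cdc6 (-2.49), the cyclin gene Ccne2 (-2.36) and the checkpoint kinase gene Bub1 (-2.25) were also lower.

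**Figure D2:**
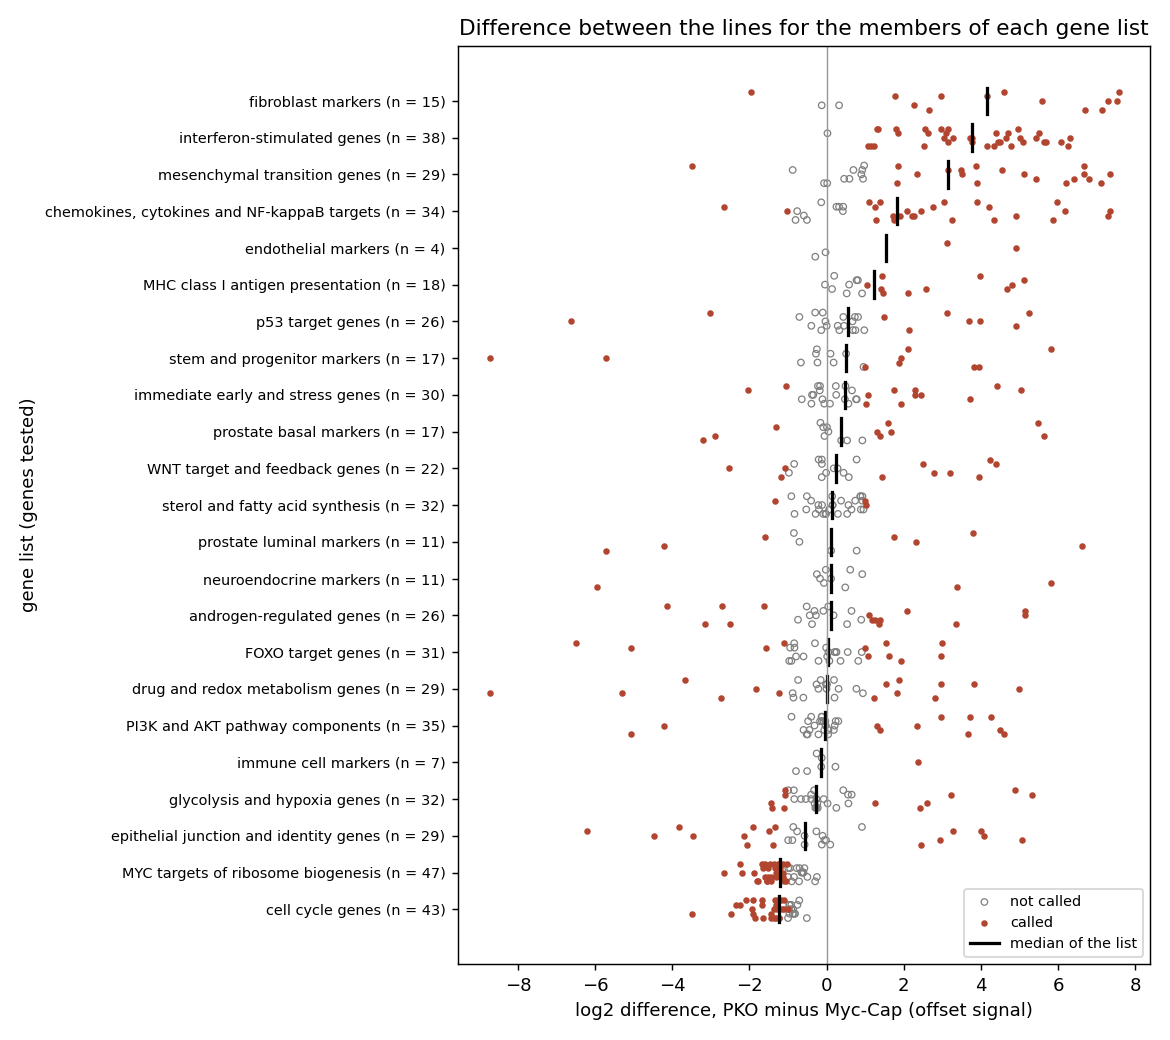
Log2 difference, PKO minus Myc-Cap, of each tested member of the 23 gene lists; filled points are called genes, open points are genes not called, black bars are list medians, and lists are ordered by median. Medians run from -1.24 for cell cycle genes to 4.17 for fibroblast markers, and 37 of the 38 interferon-stimulated genes are called, all higher.

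Lists of p53 targets and of stress genes also stood above the other genes at the preset correlation. Of 26 tested p53 target genes 7 were called higher and 2 lower (median 0.56, camera adjusted p = 0.00886, lost with an estimated correlation at adjusted p = 0.175). The tetraspanin gene Cd82 (5.25), the kinase gene Plk2 (4.90) and Tap1 were higher, and Pmaip1, which encodes the pro-apoptotic protein Noxa, was 98.0-fold lower. Of 30 tested immediate early and stress genes 10 were called higher and 2 lower (median 0.48, camera adjusted p = 0.0227, lost with an estimated correlation at adjusted p = 0.188). Egr1 was 33.0-fold higher, Egr2 was higher by 4.41, Fos by 3.71 and Nr4a2 by 2.44. Of the 5 other probe sets of Nr4a2, 3 were higher by 1.39 to 2.63 and 2 differed by -0.22 and -0.092.

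Androgen-regulated genes went both ways, with 9 of 26 tested members called higher and 5 lower (median 0.11, camera adjusted p = 0.450, and 0.451 with an estimated correlation). Pmepa1 and Ndrg1 were 35.4-fold and 35.2-fold higher in PKO cells and Zbtb10 was higher by 3.35, whereas the BMP receptor gene Bmpr1b was 17.7-fold lower. Fkbp5, a widely used androgen receptor target, was lower (-2.70, at 10.19 ± 0.17, SD, n = 3, against 12.89 ± 0.061, SD, n = 4), and was named after its value was seen. The call of Tmprss2 (1.18) rests on a probe set of a type that can detect several transcripts, while its 3 other probe sets lay near background in both lines.

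PI3K and AKT pathway components had 9 of 35 tested members called higher and 2 lower. Their mean was 0.44, their median -0.031, and camera placed them higher (adjusted p = 0.450, and 0.657 with an estimated correlation). The receptor genes Pdgfrb (4.61) and Fgfr1 (4.50) and the regulatory subunit gene Pik3r3 (4.27) were higher, and Erbb3 was 33.7-fold lower. FOXO target genes had 7 of 31 tested members called higher and 4 lower, with a mean of -0.13, a median of 0.049 and a camera placement above other genes (adjusted p = 0.450, and 0.657 with an estimated correlation). The pyruvate dehydrogenase kinase gene Pdk4 was 90.3-fold lower and Erbb3, which is in both lists, was also a member, whereas Sesn3 and Bcl6 were higher by 2.99 and 2.97. Of 11 tested neuroendocrine markers 2 were called higher, Sox2 (5.82) and Eno2 (3.38), and 1 lower, Uchl1 (-5.94) (median 0.12, camera adjusted p = 0.247, and 0.305 with an estimated correlation).

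Stem and progenitor markers had 7 of 17 tested members called higher and 2 lower (median 0.51, camera adjusted p = 0.117, and 0.281 with an estimated correlation). Sox2 and Nes (3.96) were higher and Aldh1a1 and Psca lower. WNT target and feedback genes had 7 of 22 called higher and 3 lower (median 0.23, camera adjusted p = 0.117, and 0.238 with an estimated correlation). The secreted modulator gene Dkk2 (4.39), the receptor gene Fzd1 (4.24), Tnfrsf19 (3.95) and the feedback gene Axin2 (3.20) were higher. Without a filter on low values this list passed (adjusted p = 0.0353). Sterol and fatty acid synthesis genes had 2 of 32 called higher, Acss2 (1.03) and Hmgcs1 (1.00), and 1 lower, Pmvk (-1.34) (median 0.15, camera adjusted p = 0.0744, and 0.175 with an estimated correlation). Of the other probe sets of Acss2, 1 was higher (1.06) and 1 lower (-1.17) in PKO cells. Without Myc-Cap replicate 1, 0 of the sterol genes were called higher, and without Myc-Cap replicate 2 or Myc-Cap replicate 3, 1 was. The sterol list passed without PKO replicate 1 (adjusted p = 0.0458), with no filter (0.0315) and with a 70th percentile filter (0.0281).

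Glycolysis and hypoxia genes had 6 of 32 tested members called higher and 5 lower. Their mean was 0.29, their median -0.26, and camera placed them lower (adjusted p = 0.581, and 0.736 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase gene, was 39.9-fold higher, Epas1, which encodes HIF-2 alpha, was higher by 4.88, and Slc16a3 and Car9 by 3.22 and 2.59. Drug and redox metabolism genes had 8 of 29 called higher and 6 lower, with a mean of -0.13, a median of -0.0012 and a camera placement above other genes (adjusted p = 0.581, and 0.736 with an estimated correlation). Aldh3a1 (4.995) and the efflux pump gene Abcg2 (3.82) were higher, whereas the efflux pump gene Abcb1b was 39.7-fold lower (5.48 ± 0.077, SD, n = 3, against 10.79 ± 0.045, SD, n = 4). In all 23 lists the counts adjusted over the list alone were equal to those over all genes tested. With camera's preset correlation 9 of 22 lists passed, and with an estimated one 3 did: interferon-stimulated genes, mesenchymal transition genes, and chemokines, cytokines and NF-kappaB targets. Of 49 named genes with a further probe set above the filter, 12 had at least 1 that did not move the same way by at least 1. They were Acss2, Axin2, Bub1, Cd82, Cxcl12, Dpysl2, Grhl2, Hmgcs1, Nr4a2, Tap1, Tnfaip2 and Zbtb10. Further probe sets under the filter were not counted, such as those of Tnfrsf19, Fzd1, Epas1 and Erbb3, which differed by less than 1. A probe set near background passes the filter only if it is high in a line. The count therefore cannot decide whether the probe sets of the other named genes agree.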

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

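Tests of immune cells, array processing, fibroblasts, and probe variants within single lists were chosen after the results they bear on were seen. Among all 35 splits of the 7 arrays into 3 and 4, 1 split, the real one, called as many as 3294 genes. The highest of the others called 0. Every other split mixed the lines within a group, which put the line difference into the spread of that group. The comparison therefore cannot decide on chance for this count. Nor is chance excluded for the number of gene lists past the threshold: 10 of the 35 splits gave at least 9 lists, and the highest of the others gave 11. The other splits were not free of the line difference, since each carried from 16.7% to 75% of it in either sign.

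Interferon-stimulated genes were higher in PKO cells by a median of 3.77. Immune cells in the cultures are argued against by 24 immune markers, as far as their probe sets can detect them. The median difference of these markers without a filter was -0.13, and 22 of them differed by less than 1. Cd74 (2.37) and Ctss (1.68, under the filter) were higher, and the abundant myeloid transcript Lyz2 was at 6.03. As 7 of the 24 lay above the filter, most of these values do not show that the probe sets can detect their transcripts. Array processing is argued against by 42 bacterial and phage control probe sets, whose largest absolute difference was 0.59. Of 15 called members with another probe set above the filter, 14 (93.3%) had another that rose by at least 1. The filter acts on the mean over both lines. A probe set under the filter value in Myc-Cap cells passes it only if it is higher in PKO cells. These counts therefore cannot decide on probe variants of a strain. Interferon made by the PKO cells cannot be told apart from other causes: 0 of 3 interferon ligand genes above the filter were called higher, which by the bound first written counted against it. That bound was replaced after the values were seen, as too simple, because Ifnz was higher by 0.65 (adjusted p = 1.12e-07) and most ligand genes lay near background. The other 2 were Ifna5, which was lower (-0.34, adjusted p = 0.000657), and Ifna1, which differed by 0.041 (adjusted p = 0.624). An interferon response kept active within PKO cells, by Pten loss or another difference between the lines, stays open and untested.

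Mesenchymal transition genes and fibroblast markers were higher in PKO cells; the call of the fibroblast markers was lost with an estimated correlation (adjusted p = 0.0544). Of 18 called higher members with another probe set above the filter, 18 (100%) had another that rose by at least 1. As for the interferon list, the filter itself favours probe sets that are higher in PKO cells, so this cannot decide on probe variants. Fibroblasts in the PKO cultures cannot be told apart from a program of the PKO cells themselves. Of 20 fibroblast markers 13 were higher by at least 1 without a filter, and 7 were not. Col1a2, an abundant fibroblast transcript, differed by 0.32, but its 3 probe sets lay near background in both lines, so the values do not show that they can detect it. The same holds for Thy1 (5.91 in PKO cells) and Fap (6.00), and Lum was higher by 1.31 but reached only 6.73. Epithelial genes such as Krt18 (6.61), Krt8 (3.79), Trp63 (5.63), Dsp (4.01) and Dsc2 (5.07) were higher too, and others such as Grhl2 (-6.22), Lsr (-4.46) and Cldn3 (-3.83) lower, with 6 of the 29 epithelial junction and identity genes called higher and 10 lower. Fibroblasts do not supply the epithelial genes that were higher. Whether a culture of epithelial cells with fibroblasts would show both directions was not tested. A program of the PKO cells was not tested.

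For the 3294 called genes as a whole, sequence variants of a mouse strain under a probe stay open. Of 1536 called genes with another probe set above the filter, 70.8% had another that moved the same way by at least 1, between the bounds of 50% and 80% set for this test. In 3 genes all other probe sets moved the opposite way by at least 1. A further probe set can also measure another transcript form or lie near background, which keeps the test from deciding. The biological difference between the lines, in Pten, in the MYC transgene or in origin, was not tested apart from it.

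In 9 of 106 tested values, 100 named genes and 6 array measures, 1 Myc-Cap array lay far from the other 3, by a gap that takes more of the range than Dixon's 95% critical value; chance flags about 1 in 20. The gap was 0.909 of the range for Myc (Myc-Cap replicate 1 at 8.71, the others from 9.08 to 9.12), 0.957 for Dsg2, 0.839 for Psmb8, 0.841 for Epas1 and 0.833 for Egr1, where it was also replicate 1. It was 0.952 for Aldh1a7 and 0.891 for Axin2 (replicate 3), 0.839 for Krt18 (replicate 4) and 0.973 for Nr4a2 (replicate 2). Apart from Myc, Psmb8 (7.63 against 7.86 to 7.90), Epas1 (7.01 against 7.40 to 7.48) and Egr1 (8.31 against 8.57 to 8.63), these gaps were at most 0.20 wide.

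Values outside the comparison of genes were also set against the lines. Of 3430 probe sets above the filter with no entry in the annotation table, 722 were called (21.0%), 409 higher and 313 lower, with differences from -7.25 to 7.59. Hybridization controls were higher on PKO arrays by 0.25 and poly-A controls lower, with a difference of -0.41.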

How the results depend on the processing

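The 3294 called genes, 50.2% of them higher in PKO cells (95% exact binomial interval 48.5% to 52.0%), gave counts from 2764 to 3503 under normalization, offset, filter removal, probe set averaging, array weights, treat and eBayes without trend. The interval treats genes as independent, which they are not, and does not measure the spread between arrays or lines. A 70th percentile filter, which tests fewer genes, called 1742 with 36.7% higher, all of them among the 3294. It left 639 of 1655 higher calls and 1103 of 1639 lower calls. Its mean over 4 Myc-Cap and 3 PKO arrays removes genes low only in Myc-Cap cells more readily than genes low only in PKO cells. This share therefore does not show that well-expressed genes mostly fall in PKO cells. Probe sets tested one by one called 6621 (3969 distinct genes) with 47.8% higher. No size threshold called 10612 with 42.3% higher and also passed Myc (0.91). The share was 47.5% with scaling to a common median, 52.3% with 4 times the offset, 52.1% without a filter, 47.5% with the mean of probe sets and 52.5% with treat; the cause was not tested. Myc stayed between 0.81 and 0.96. Of lists, 9 passed, against 3 with an estimated correlation, 21 with fry's directional test and 22 with its mixed test, which ask whether a list's own genes move and not whether they exceed other genes. As 10612 of 12356 tested genes had an adjusted p under 0.05 in limma, a pass of the mixed test does not set a list apart. Under fry's directional test 4 lists that had not passed did so against camera's direction, which is relative to other genes: prostate luminal markers (mean 0.21, adjusted p = 9.87e-06) and drug and redox metabolism genes (mean -0.13, adjusted p = 7.17e-08) as lower, immune cell markers (mean 0.11, adjusted p = 0.000514) and glycolysis and hypoxia genes (mean 0.29, adjusted p = 0.0228) as higher; the cause was not tested. No called named gene, measure or other list that passed was reversed. With probe sets tested one by one, each gene was followed by its own probe set; another one of Acss2 was lower (-1.17). Without an offset another probe set stood for Gfra2 (3.13), Vcam1 (5.10) and Dclk1 (6.90), which had been higher by 8.04, 7.34 and 7.55. Of the named genes, Acss2 and Hmgcs1 lost their call under some alternative in which they were tested.

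With each array left out in turn, 3240 to 3348 genes were called, 48.8% to 51.9% of them higher, Myc differed by 0.81 to 0.95, and 9 or 10 lists passed. Array medians differed by 0.0470 to 0.0567, hybridization controls by 0.236 to 0.262 and poly-A controls by -0.442 to -0.367, none past 0.05, since fewer arrays cannot give an exact p under 0.0667. After quantile normalization the Gapdh ratio differed by -0.0554 (exact permutation p = 0.0286).

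With the replicate block 3291 genes were called, 3266 of them shared with the fit without it, and 9 lists passed. Number 4 occurs only among the Myc-Cap arrays, so with the block that array adds nothing to the difference. Myc differed by 0.946 with the block, as it did without Myc-Cap replicate 4. The numbers do not pair the samples: deviations of arrays with the same number correlated at -0.000308, -0.113 and 0.0546, and 0 of 6 arrays correlated best with their own number. Signal near background limits genes that are low in both lines. The filter left out those with a mean under its value, but not all of them. Col1a2, near background in both lines, was still tested.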

Other observations

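The genes in the following values were picked after their values were seen, as were the tests of Myc and of whole chromosomes. Genes that sense nucleic acids or receive interferon differed unevenly. Sting1, the adaptor of cytosolic DNA sensing, was 6.06-fold higher in PKO cells (11.77 ± 0.0054, SD, n = 3, against 9.17 ± 0.11, SD, n = 4), and its other probe set was higher by 2.59. Cgas, the DNA sensor upstream of it, was lower (-1.54, adjusted p = 8.16e-12 in limma). The interferon receptor gene Ifnar2 was higher by 1.12, and Ifnar1 differed by 0.22, Irf3 by 0.10 and the RNA sensor gene Tlr3 by 0.73, each under the size threshold.

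Among tumour suppressor genes, Cdkn2a was 23.8-fold lower in PKO cells (7.10 ± 0.11, SD, n = 3, against 11.67 ± 0.032, SD, n = 4) and its neighbour Cdkn2b 5.66-fold lower. Mtap, a further neighbour, was 2.76-fold higher, and its 4 probe sets rose by 1.47 to 2.05. Rb1 was higher by 1.24, and Smad4 differed by -0.17. The transferrin receptor gene Tfrc, which takes up iron, was lower (-1.82), as were its other probe sets (-2.67 and -3.27).

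Targets of MYC in ribosome biogenesis were lower in PKO cells at camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.0814). A lower mouse Myc transcript is a candidate explanation that the values argue against, since Myc was higher by 0.91. Whether the probe set also detects the human MYC transgene of Myc-Cap cells was not examined. If the probe set does, transgene signal would add to the Myc-Cap value only, and mouse Myc would still be higher in PKO cells. If the probe set does not, its value does not bear on the dose of the transgene. That dose was not tested as a cause. MYC protein and growth rate were not measured, so the lower targets stay unexplained.

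Copy number differences between the lines may add to the difference along chromosomes. Of 11809 windows of 25 neighbouring tested genes, 12 had a median that passed the limit of 95% of 1000 shuffled gene orders (0.99 from the overall median). They joined into 1 region on chromosome 9, from Pgm3 to Nmnat3, where 17 of 41 genes were called higher and 0 lower. The region holds relatives that could share regulation, such as Plscr1 (1.30), Plscr2 (3.26) and Plscr4 (5.45), and the largest window of all shuffled orders, 1.45, exceeded the largest observed, 1.35. Of 20 chromosomes 8 had a median that departed from 10000 shuffled gene positions at an adjusted p under 0.05. Chromosomes 18, 1, 13, 8 and 10 lay above the overall median, by 0.21, 0.21, 0.15, 0.082 and 0.076, and chromosomes 5, 2 and X below it, by -0.16, -0.14 and -0.11. Copy number itself was not measured, and neighbouring genes that share regulation would give such shifts too.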
